A study of Homo sapiens with 30 samples.

How the data were processed

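The samples were human dendritic cells grown from blood monocytes of 5 healthy donors. Per the labels' protocols, the cells were cultured with GM-CSF and IL-4, each at 50 ng per ml, and were stimulated on day 7 with vehicle or with recombinant soluble CD40 ligand (sCD40L) at 1 µg per ml. RNA was taken 1, 3 or 24 h later, so that 2 treatments at 3 times gave 6 groups of 5 donors and 30 arrays. Per the labels' protocols, RNA was purified in a multi-well format with RNeasy chemistry, amplified with the NuGEN Ovation Pico WTA System V2 and hybridised to Affymetrix HT-HGU133 Plus PM arrays, which carry perfect-match probes alone.

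The authors deposited 1 value per probe set and array on a log2 scale. RMA, which corrects background, applies quantile normalization and summarises the probes of a set, is named in the submitters' processing notes; its software and version are not given in the sources used here. The log2 scale was read from the deposited values themselves, which ran from 1.26 to 13.64 over the 30 arrays. Quantile normalization makes the arrays alike in their distributions, so a change shared by most genes cannot be seen, and a large change in one direction can move the share of genes called higher or lower. RMA also compresses differences of dim probe sets. For arrays, their number limits the precision: each group had 5.

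The table held 54715 probe sets. Of these, 102 were control probe sets. Of the others, 40914 had 1 gene symbol in the platform annotation, 864 had several and 12835 were unnamed here. The Entrez IDs of 40858 probe sets with 1 gene (99.86%) were found in a RefSeq gene table, which was used for current names only. That table is of assembly GRCh38.p14, no build is named with the deposited values, and no coordinates are given here. Control probe sets, those without a single symbol, and 59 probe sets of XIST, TSIX or genes on the Y chromosome were left out. A probe set was kept if it was above the median of all probe sets of its array on at least 5 of the 30 arrays, which left 26060 probe sets. The kept probe set with the highest mean over all arrays represented each gene. This gave 14318 genes for testing, of 19738 with a probe set before the filter; 6688 genes had more than 1 kept probe set. Affymetrix marks with _x_ and _s_ in their names the probe sets whose probes can also match other sequences or several transcripts.

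The fit was made in R 4.3.3 with limma 3.58.1: a linear model with 6 groups and the donor as a block on all 30 arrays, contrasts, and eBayes moderation (20 residual and 4.39 prior degrees of freedom). All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 14318 genes of each comparison, with 0.05 as the threshold. Log2 fold changes are differences of group means within donors, with their standard error (SE). Each SE rests on 1 spread per gene pooled over all 30 arrays, not on the arrays of the compared time alone. An n given with an SE is the number of donors. The comparisons were sCD40L against vehicle at each of the 3 times, the difference of that effect between each pair of times, and vehicle at 3 h and at 24 h against vehicle at 1 h. Replicates are separate donors, and the series' design text states that each donor gave cells to every group. As a check of the pairing by donor label, arrays were correlated after each group's mean was subtracted: within a donor the correlation was 0.205 at the lowest and 0.554 at the median, against a median of -0.171 between arrays of different donors and groups. All 30 arrays correlated best with an array of their own donor. No 2 arrays held identical values.

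Lists of genes were fixed for 34 functions and cell types, 9 of them markers of cell types that a monocyte culture could hold. For each list, members past the threshold were counted over all genes and with p-values adjusted over the list alone. The list as a whole was tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation. Camera p-values were adjusted over all lists and over the comparisons of 1 kind (3 for sCD40L, 3 for differences between times, 2 for vehicle). Lists with fewer than 5 measured members were not tested, which left out the erythroid markers. Differences of a list's mean effect between times were also tested with limma on the 5 donors' list means. A list mean is given with its SD over the 5 donors.

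The genes named follow a rule. For each sCD40L comparison they are the 15 largest increases and the 10 largest decreases among genes past the threshold with the same sign in all 5 donors, CD40 itself, and up to 4 members with the smallest p of each list described, past the threshold or not. For each difference between times they are the 5 largest in each direction, and for each vehicle comparison the 8 largest in each direction with the same sign in all 5 donors. The design, this rule, the lists, the filter, the comparisons and most alternatives were chosen before the data were examined; 2 alternatives were added afterwards. These were a covariate for RNA quality, the difference between the 3' and 5' control probe sets of ACTB on each array, and arrays shifted so that the median deviation of the tested genes was 0.

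The alternatives chosen beforehand were no block, a block for each donor and time, the arrays of the compared times alone, no filter and a stricter filter (mean above the 60th percentile), all kept probe sets, the mean of a gene's probe sets, no _x_ and _s_ probe sets, a second quantile normalization, arrays centred on their medians, eBayes with trend and robust options, array weights, an added limit of 1 on the absolute log2 fold change, and each replicate (donor) left out in turn with all 6 of its arrays.

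The procedure was tested on simulated data for 14318 genes with 50 genes changed at each size; this test was first run after the fit to the real arrays. At 1 h it recovered 46%, 90%, 100% and 100% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, with 4.55% false calls. At 3 h it recovered 60%, 94%, 100% and 100%, with 5.35% false calls. At 24 h it recovered 38%, 92%, 100% and 100%, with 5.71% false calls. For the difference between 3 h and 1 h it recovered 28%, 88%, 98% and 100%, and for that between 24 h and 3 h 8%, 74%, 100% and 100%. Camera, simulated for the 24 h comparison with lists of random genes, found 5 of 5 shifted lists among 33 with 0 false lists. The simulated noise was independent between genes. It therefore cannot show how often the preset correlation gives false lists where genes are correlated.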

Results

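Gene expression was measured in immature dendritic cells (DC) grown from monocytes of 5 healthy donors and exposed to vehicle or to sCD40L, the soluble form of the T-cell ligand of the receptor CD40. DC capture antigen and, once matured by such signals, present it to T cells. The design asked which transcripts of DC change after CD40 ligand, and when. Each of the 6 groups (vehicle and sCD40L at 1, 3 and 24 h) held 5 arrays, 1 per donor. Array medians lay between 5.09 and 5.14 on the log2 scale and interquartile ranges between 2.58 and 2.78. With sCD40L the interquartile range changed within donors by -0.0548 ± 0.0357 at 3 h and -0.0714 ± 0.0476 at 24 h (SD, n = 5). The median changed by 0.0192 ± 0.00709 and 0.0156 ± 0.00627. Each of these had the same sign in all 5 donors (exact paired permutation p = 0.0625, two-sided, the smallest that 5 pairs allow). Probe sets of the array's nonspecific controls had a median of 2.52. Pearson's r over the genes tested was at least 0.924 between arrays of 1 group.

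Of 14318 genes tested with limma, 270 passed the threshold at 1 h (154 higher and 116 lower with sCD40L), 1923 at 3 h (669 higher and 1254 lower) and 3427 at 24 h (1291 higher and 2136 lower). Changes of at least 2-fold were mostly increases at the early times: 85 genes were higher and 8 lower at 1 h, 196 higher and 62 lower at 3 h, and 336 higher and 255 lower at 24 h. In all, 4654 genes passed at 1 or more times and 84 at all 3 times, of which 65 were higher and 14 lower throughout. Of the 154 genes higher at 1 h, 121 were also higher at 3 h (7.2 by chance), and of the 116 genes lower at 1 h, 35 were also lower at 3 h (10.2 by chance). Of the genes past the threshold at 3 h, 293 of 669 higher genes were higher at 24 h (60.3 by chance) and 431 of 1254 lower genes were lower at 24 h (187 by chance). Of the 154 genes higher at 1 h, 72 were higher at 24 h (13.9 by chance) and 6 lower. Of the 116 genes lower at 1 h, 27 were lower at 24 h (17.3 by chance) and 6 higher. These chance values take the calls at 2 times as independent, though they share the donors and 1 spread per gene. The share of higher genes at 3 h was 34.8%, and it was 30.9% with arrays centred on their medians, 38.7% after a second quantile normalization and 45.3% with arrays centred on the tested genes. At 1 h the balance turned with array weights (265 higher and 270 lower), and without replicates 1, 3, 4 and 5 the lower genes numbered 62, 71, 73 and 49. At 24 h the share was 37.7%, and 51.1% (598 higher and 572 lower) with the ACTB covariate and 47.3% without the donor block.

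**Figure D1:**
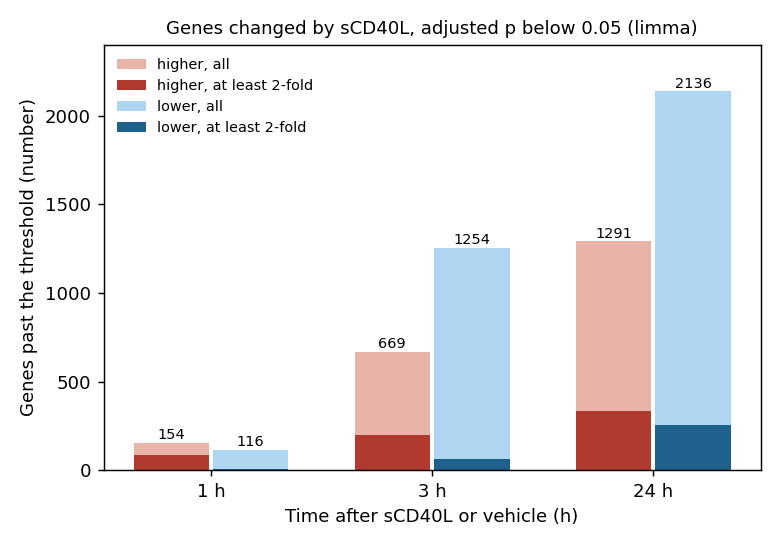
Number of genes higher and lower with sCD40L than with vehicle at 1, 3 and 24 h (adjusted p below 0.05), for all genes and for those changed at least 2-fold. The bars grow from 154 higher and 116 lower genes at 1 h to 1291 higher and 2136 lower genes at 24 h.

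CD40, the receptor for the ligand, was already expressed in vehicle-treated DC (log2 level 9.39 ± 0.39 at 1 h, SD, n = 5). It rose 3.31-fold at 3 h (log2 difference 1.73 ± 0.16, SE, adjusted p = 1.56e-07) and 2.60-fold at 24 h (1.38 ± 0.16, adjusted p = 1.35e-06). At 1 h the difference was 0.62 ± 0.16 and just missed the threshold (adjusted p = 0.0505). It had the same sign in all 5 donors at each time. The 1 h value passed under 10 of 19 alternatives, the fit without replicate 4 among them (0.69, adjusted p = 0.0325), and its adjusted p ranged from 4.26e-05 to 0.682 over the 19.

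Within 1 h of sCD40L, DC held far more mRNA of pro-inflammatory cytokines. IL1B, a secreted mediator of inflammation, was 16.5-fold higher than with vehicle (log2 difference 4.05 ± 0.44, SE, n = 5), and IL12B, a subunit of cytokines that steer T cells, was also 16.5-fold higher (4.04 ± 0.50). TNF rose 5.94-fold, the macrophage growth factor CSF1 3.59-fold, and IL1A 16.1-fold on its brightest probe set. Chemokine transcripts rose as well: CCL20, which attracts immature DC and lymphocytes, 11.6-fold, the neutrophil attractants CXCL1 6.54-fold, CXCL3 5.53-fold and CXCL8 2.97-fold, and CCL4 3.34-fold. Among the other large increases were MIR155HG, the precursor transcript of microRNA-155 (11.5-fold), TNFAIP6, a secreted hyaluronan-binding protein (8.42-fold), PTGS2, the inducible enzyme of prostaglandin synthesis (8.41-fold), F3, the coagulation initiator tissue factor (7.21-fold), and EREG, a growth factor of the epidermal growth factor family (5.33-fold). TNFSF9, the ligand of a costimulatory receptor, rose 5.60-fold. Each of these passed the threshold with the same sign in all 5 donors, with adjusted p of at most 0.00479.

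The gene lists showed the same early programme as groups. Of the 23 measured NF-kB subunits, inhibitors and direct targets, 14 rose (20 when adjusted over the list alone) and none fell, with a mean log2 change of 1.11 ± 0.23 (SD over donors, camera adjusted p = 1.48e-42). They included BCL2A1, which protects cells from apoptosis (5.56-fold), and the inhibitors of NF-kB signalling TNFAIP3 (6.27-fold), NFKBIA (3.54-fold) and NFKBID (4.70-fold). Of 24 cytokines 7 rose (10 adjusted over the list alone; mean 1.04 ± 0.38, adjusted p = 3.3e-15), and of 22 chemokines 5 rose (8 adjusted over the list alone; mean 0.83 ± 0.36, adjusted p = 4.38e-09). Immediate early genes rose in 8 of 25 cases (13 adjusted over the list alone; mean 0.64 ± 0.14, adjusted p = 5.25e-21), among them the phosphatases DUSP2 (4.61-fold) and DUSP5 (1.78-fold), PPP1R15A (2.78-fold) and ZFP36, which destabilises cytokine mRNA (2.44-fold). Of 24 negative regulators of signalling 6 rose (9 adjusted over the list alone; mean 0.46 ± 0.12, adjusted p = 4.7e-13), with the cytokine-signalling inhibitor SOCS3 2.17-fold higher. Of 25 DC maturation genes 8 rose (12 adjusted over the list alone; mean 0.55 ± 0.062, adjusted p = 2.62e-17), including the adhesion molecule ICAM1 (3.65-fold), the actin-bundling protein FSCN1 (2.14-fold) and the checkpoint ligand CD274 (1.55-fold). None of the members measured passed the threshold as lower in these lists.

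Smaller shifts at 1 h were found in 6 further lists. Of 17 genes of prostaglandin and tryptophan metabolism 4 rose (4 adjusted over the list alone; mean 0.37 ± 0.076, adjusted p = 0.000581): PTGS2, the prostaglandin receptors PTGER4 (2.32-fold) and PTGER2 (1.79-fold), and NAMPT (1.70-fold). Of 20 apoptosis regulators 2 rose (adjusted over the list alone, 4 rose and 1 fell; mean 0.23 ± 0.046, adjusted p = 0.00306), both of them known to oppose cell death, BCL2A1 and CFLAR (1.86-fold), while PMAIP1 (log2 difference 0.75, adjusted p = 0.0745) and TNFRSF10B (0.39, adjusted p = 0.14) did not pass. Of 19 components of CD40 signalling 2 rose, the adaptor TRAF1 (3.34-fold) and the kinase MAP3K14 (2.61-fold); adjusted over the list alone 3 rose and 1 fell (mean 0.22 ± 0.059, adjusted p = 0.00376, adjusted p = 0.123 with an estimated correlation). TRAF6, at -0.51, did not pass over all genes (adjusted p = 0.187). Of 19 interferon-gamma-type genes 2 rose (3 adjusted over the list alone), the transcription factor IRF1 (4.42-fold) and SOCS3 (mean 0.21 ± 0.077, adjusted p = 0.00963, adjusted p = 0.134 with an estimated correlation); CXCL10 (0.88, adjusted p = 0.178) and SOCS1 (-0.41, adjusted p = 0.48) did not pass. The unfolded protein response list had 2 of 21 members higher (4 adjusted over the list alone), the stress sensor ERN1 (1.57-fold) and EDEM1 (1.39-fold), while XBP1 (0.54, adjusted p = 0.0829) and ATF4 (0.33, adjusted p = 0.143) did not pass (mean 0.12 ± 0.07, adjusted p = 0.0172, adjusted p = 0.393 with an estimated correlation). Of 15 heat shock proteins DNAJB4 alone rose (2.06-fold; 1 adjusted over the list alone), and HSPA1A (0.25, adjusted p = 0.729), DNAJB1 (0.29, adjusted p = 0.749) and HSPB1 (0.22, adjusted p = 0.802) did not pass (mean 0.15 ± 0.13, adjusted p = 0.0371, adjusted p = 0.437 with an estimated correlation).

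The largest decreases at 1 h were the following. HHEX, a homeobox factor of blood cell development, fell by 1.86 ± 0.34 on the log2 scale (SE, n = 5), and PDK4, a kinase that restrains glucose oxidation, fell by 1.49 ± 0.26. Zinc finger genes made up 6 of the 10 largest decreases: ZNF709 fell by 1.43, ZNF627 by 1.26, ZNF441 by 1.24, ZNF823 by 1.12, ZNF564 by 1.07 and ZNF567 by 1.00. FRAT2, a regulator of Wnt signalling, fell by 1.23 and ID3, an inhibitor of helix-loop-helix transcription factors, fell by 0.96. All had the same sign in 5 of 5 donors, with adjusted p of at most 0.0135.

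Without the donor block 114 genes passed at 1 h, and 18 named genes were lost (adjusted p = 0.0575 to 1): EREG, PDK4, ZNF709, ZNF627, ZNF441, ZNF823, ID3, FSCN1, TRAF1, MAP3K14, CSF1, DUSP5, ERN1, EDEM1, DNAJB4, CFLAR, PTGER4 and NAMPT. Without replicate 5 the count was 157 instead of 270. In that fit CXCL1 (adjusted p = 0.0646), CXCL3 (0.0758), CXCL8 (0.0524), TNF (0.0638), ERN1 (0.0518), DNAJB4 (0.0578), NAMPT (0.0638), ZNF709 (0.0638) and ZNF823 (0.097) no longer passed. ZNF823 and DNAJB4 were also lost without replicate 4 (0.0939 and 0.117), NAMPT and DNAJB4 without replicate 1 (0.0778 and 0.0696), EDEM1 and NAMPT without replicate 2 (0.193 and 0.0512), and EDEM1, ZNF709 and ZNF823 without replicate 3 (0.109, 0.0514 and 0.0804). EDEM1 was also lost with the 1 h arrays alone (0.0779). Over the 19 alternatives the adjusted p of these 10 genes lay between 2.27e-05 and 0.856. XBP1 and PMAIP1 passed without replicate 2 (0.0133 and 0.00904; 0.00904 to 1 over the alternatives). Of the named genes not past the threshold at 1 h, 5 passed with array weights and 5 with a block for each donor and time. With the 1 h arrays alone 4 did. The unfolded protein response list was lost without replicate 3 (0.0979) and with all kept probe sets (0.147), and the heat shock list without replicate 1 (0.0945) or 3 (0.178), with 0.00849 to 0.178 over the alternatives of both. With _x_ and _s_ probe sets left out, IL1A had a log2 difference of 0.45 (0.163) and ZNF627 of -0.15 (0.967). With the mean of a gene's probe sets, CSF1 was at 0.71 (0.0702) and ZNF627 at -0.71 (0.0656); over the alternatives the adjusted p of these 3 genes lay between 4.77e-08 and 0.967. ZNF709 and ERN1 each had 1 of 2 other kept probe sets pointing the opposite way. In EREG, IRF1, PTGER4 and HSPB1 the difference of 1 donor stood apart from the other 4 (Dixon's ratio 0.774, 0.772, 0.731 and 0.772).

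At 3 h the cytokine programme persisted and was joined by a different set of genes. PLAT, the tissue plasminogen activator, was 28.9-fold higher with sCD40L (log2 difference 4.86 ± 0.48, SE, n = 5), NXN, a thioredoxin-like oxidoreductase, 14.8-fold (3.89 ± 0.25), and SGPP2, a phosphatase of sphingosine phosphate, 12.6-fold (3.66 ± 0.28). IL12B was 18.3-fold higher, MIR155HG 14.9-fold, TNFAIP6 13.8-fold, IL1A 13.4-fold, IL1B 10.8-fold, CCL20 10.3-fold and PTGS2 6.99-fold. BCL2A1 rose 9.07-fold and TRAF1 7.00-fold. G0S2, an inhibitor of lipolysis, rose 6.64-fold, ELOVL7, an elongase of long fatty acids, 6.38-fold, and KANK1, a regulator of actin, 6.21-fold on its brightest probe set. Each passed with the same sign in all 5 donors and an adjusted p of at most 0.000332.

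Among decreases at 3 h, PDK4 fell by 2.58 ± 0.26 on the log2 scale, HHEX by 2.15 ± 0.34, and CAVIN2, a caveolar coat protein, by 2.07 ± 0.36 (SE, n = 5). KLF4, a transcription factor of the monocyte lineage, fell by 1.96, CTLA4, an inhibitory receptor that binds CD80 and CD86, by 1.70, and the adenosine receptor ADORA3 by 1.69. MBLAC2 fell by 1.72, the actin regulator JMY by 1.56, RFXAP, a factor needed for MHC class II transcription, by 1.55, and FAM117B by 1.48. TIPARP, an ADP-ribosyltransferase induced by the aryl hydrocarbon receptor, fell by 1.44. All had the same sign in 5 of 5 donors, with adjusted p of at most 0.00172.

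NF-kB targets and DC maturation genes rose at 3 h too. Of 23 NF-kB list members 19 rose and none fell (21 adjusted over the list alone; mean 1.22 ± 0.20, adjusted p = 2.53e-29), including TNFAIP3 (5.25-fold) and NFKBIA (3.70-fold). Of 25 maturation genes 16 rose (21 adjusted over the list alone; mean 0.93 ± 0.13, adjusted p = 9.07e-23), with FSCN1 4.00-fold, the receptor SLAMF1 3.39-fold and ICAM1 2.72-fold higher. Cytokines rose in 12 of 24 cases (16 adjusted over the list alone; mean 1.16 ± 0.37, adjusted p = 1.27e-12), EBI3 by 3.17-fold. Chemokines rose in 7 of 22 cases (10 adjusted over the list alone; mean 0.91 ± 0.12, adjusted p = 9.11e-08), among them the T-cell attractants CCL5 (5.42-fold) and CCL1 (5.37-fold) and the neutrophil attractant CXCL8 (3.56-fold). Of the CD40 signalling components 7 of 19 rose (7 adjusted over the list alone; mean 0.44 ± 0.096, adjusted p = 3.29e-05), with MAP3K14 2.88-fold and the ubiquitin ligase BIRC2 1.80-fold higher. Of 24 negative regulators 11 rose and 2 fell (12 and 4 adjusted over the list alone; mean 0.38 ± 0.099, adjusted p = 1.43e-06), including TNIP1 (2.27-fold) and DUSP5 (1.69-fold). Of 17 prostaglandin and tryptophan genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; mean 0.35 ± 0.096, adjusted p = 0.0021), KYNU by 2.02-fold and PTGER4 by 2.32-fold.

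Weaker list results at 3 h were the following. Of 19 interferon-gamma-type genes 6 rose and 1 fell (6 and 2 adjusted over the list alone), with GBP1 2.77-fold, IRF1 2.66-fold, the peptide transporter TAP1 1.97-fold and IRF8 1.77-fold higher (mean 0.30 ± 0.12, adjusted p = 0.00306, adjusted p = 0.0869 with an estimated correlation). The unfolded protein response list had 4 of 21 members higher (4 higher and 1 lower adjusted over the list alone), EDEM1, XBP1, ATF4 and CHAC1, by 1.33-fold to 1.62-fold (mean 0.15 ± 0.093, adjusted p = 0.0173, adjusted p = 0.393 with an estimated correlation). Of 20 apoptosis regulators 7 rose and 4 fell, over all genes and adjusted over the list alone. Besides the protective BCL2A1 and CFLAR (2.41-fold), the pro-apoptotic BID rose 2.02-fold, and the pro-apoptotic BCL2L11 fell by 0.74. This list had a mean of 0.30 ± 0.088 and a median of -0.003 (adjusted p = 0.0492, adjusted p = 0.0733 with an estimated correlation). Of 25 immediate early genes 3 rose (3 adjusted over the list alone), DUSP5, DUSP2 (2.53-fold) and IER5 (1.39-fold), and FOSL1 did not pass (0.73, adjusted p = 0.0991; list mean 0.12 ± 0.27, adjusted p = 0.0353, adjusted p = 0.393 with an estimated correlation). Of 20 cholesterol genes HMGCS1 rose 1.74-fold and STARD4 (0.67, adjusted p = 0.128), LSS (0.27, adjusted p = 0.336) and MVD (0.26, adjusted p = 0.367) did not pass; none passed adjusted over the list alone (mean 0.19 ± 0.066, adjusted p = 0.0326, adjusted p = 0.694 with an estimated correlation). Of 9 platelet markers GP1BA, a subunit of the platelet receptor for von Willebrand factor, rose 5.57-fold and GP9 1.24-fold (2 adjusted over the list alone), while GP1BB (0.20, adjusted p = 0.255) and TUBB1 (0.37, adjusted p = 0.48) did not pass (mean 0.37 ± 0.13, adjusted p = 0.023).

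At 3 h the count was 708 without the donor block, 1177 without replicate 1, 1023 without replicate 4 and 1280 without replicate 5. HMGCS1 was lost without replicate 1, 3, 4 or 5 (adjusted p = 0.078, 0.0684, 0.082 and 0.0978), IRF8 without replicate 1, 4 or 5 (0.0654, 0.0652 and 0.112), IER5 without replicate 1, 2, 4 or 5 (0.0605, 0.106, 0.108 and 0.0998), CHAC1 without replicate 3 or 4 (0.0501 and 0.111) and GP9 without replicate 1, 3, 4 or 5 (0.305, 0.203, 0.116 and 0.0579), with 0.000303 to 0.505 over the alternatives of these 5. Without the block 12 named genes were lost (0.0829 to 0.505): PDK4, CTLA4, DUSP5, DUSP2, IER5, IRF8, HMGCS1, EDEM1, XBP1, ATF4, BCL2L11 and GP9. GP9 was also lost with a block for each donor and time (0.0604), the 3 h arrays alone (0.125), no filter (0.0705), all kept probe sets (0.0572), arrays centred on their medians (0.0551) and trend and robust options (0.0605). The immediate early list was lost without replicate 1, 2 or 4 (0.0589, 0.159 and 0.0592), its mean falling to 0.054 without replicate 2, and also without the block (0.115), with no filter (0.0502) and with arrays centred on the tested genes (0.0591). The apoptosis list was lost without replicate 4 or 5 (0.0771 and 0.0731), without the block (0.0926), with a block for each donor and time (0.0524), with the 3 h arrays alone (0.108), with no filter (0.062), with array weights (0.0527), with the ACTB covariate (0.0629) and with arrays centred on the tested genes (0.0775), while its mean stayed between 0.277 and 0.339 in these fits. The unfolded protein response list was lost without replicate 4 (0.0506), the cholesterol list without replicate 3 (0.0696) and with arrays centred on the tested genes (0.0512), and the platelet list without replicate 3 (0.0914) and with the 3 h arrays alone (0.0543); over the alternatives of these 5 lists the adjusted p lay between 6.12e-12 and 0.159. With _x_ and _s_ probe sets left out IL1A was at 0.17 (0.545) and KANK1 at -0.015 (0.967), and with the mean of a gene's probe sets BCL2L11 was at -0.40 (0.171); the alternatives of these 3 genes gave 1.5e-07 to 0.967. Both other kept probe sets of KANK1, the 1 other of FAM117B and 1 of 6 others of BCL2L11 pointed the opposite way. In SGPP2, IL1B and DUSP2 the difference of 1 donor stood apart from the other 4 (Dixon's ratio 0.781, 0.74 and 0.754).

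DC maturation genes were among the largest increases at 24 h. EBI3, a subunit of heterodimeric cytokines, was 21.0-fold higher with sCD40L (log2 difference 4.39 ± 0.22, SE, n = 5), and CCR7, the receptor that guides DC to lymph nodes, 8.76-fold (3.13 ± 0.20). CYP7B1, an oxysterol hydroxylase, showed the largest increase, 29.9-fold (4.90 ± 0.45), followed by IL12B at 27.7-fold (4.79 ± 0.50). The costimulatory receptor TNFRSF9 rose 15.4-fold, CD200, the ligand of an inhibitory receptor, 13.8-fold, and the tryptophan-degrading enzyme IDO1 13.2-fold. Other large increases were those of CNN3, an actin-binding calponin, 20.2-fold, EDIL3, an integrin ligand, 15-fold, the metalloproteinase MMP10 14.6-fold, the receptor phosphatase PTPRK 13.3-fold and the desmosomal cadherin DSG2 9.16-fold. MIR155HG was 18.6-fold, the transporter SLCO5A1 10.1-fold and the antisense transcript HSD11B1-AS1 9.98-fold higher. All had the same sign in 5 of 5 donors, with adjusted p of at most 2.26e-06.

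PDK4 stayed low at 24 h, and fell by 2.24 ± 0.26 on the log2 scale (SE, n = 5). DHRS2, a short-chain dehydrogenase, fell by 2.12, the secreted glutathione peroxidase GPX3 by 2.09 and the sodium channel SCN9A fell by 2.04. The monocyte attractants CCL2 and CCL7 fell by 1.97 and 1.89. ADORA3 fell by 1.93, the kinase LRRK2 by 1.88, MAP3K5-AS2 fell by 1.85 and PKIB, an inhibitor of protein kinase A, fell by 1.79. All had the same sign in 5 of 5 donors, with adjusted p of at most 0.00289.

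**Figure D2:**
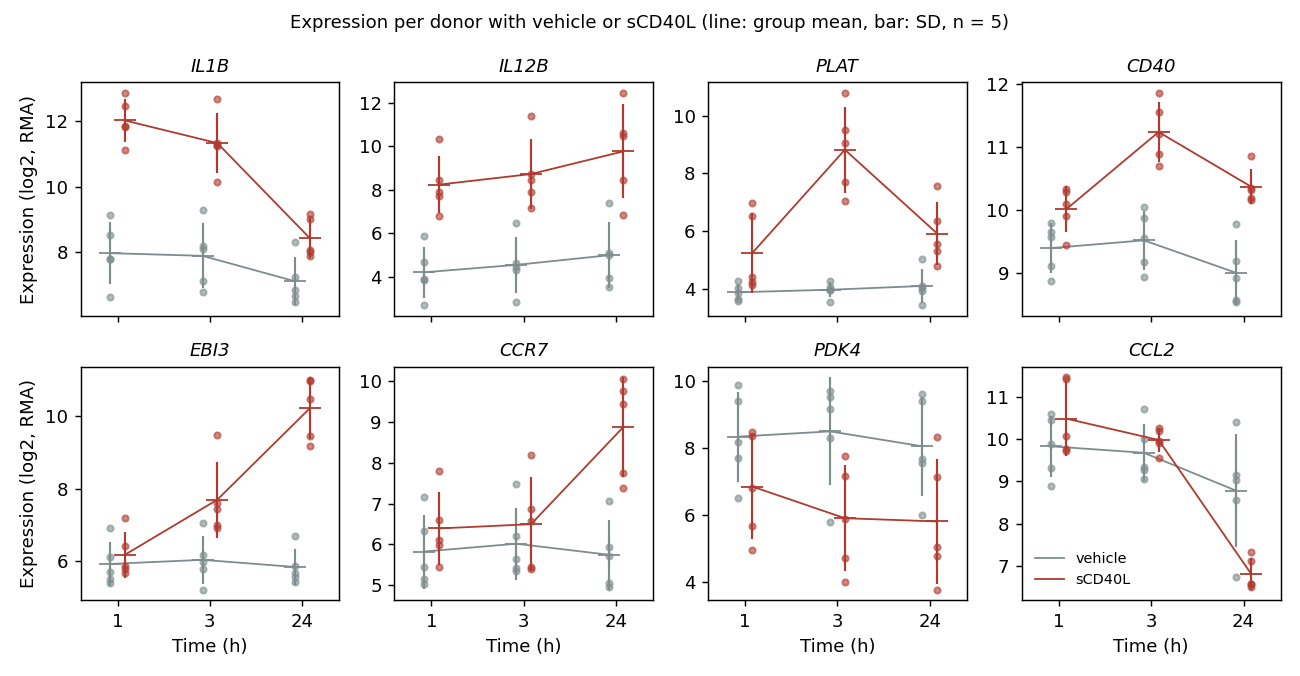
Log2 expression of 8 genes in each donor with vehicle or sCD40L at 1, 3 and 24 h (time steps drawn equally spaced; points are donors, lines join group means, bars are the SD, n = 5). IL1B was highest at 1 h, PLAT at 3 h, EBI3 and CCR7 rose most at 24 h, and PDK4 lay below vehicle on average at all 3 times.

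DC maturation genes formed the clearest group at 24 h: 21 of 25 rose, over all genes and adjusted over the list alone, and none fell (mean 1.78 ± 0.18, adjusted p = 3.05e-28), with SLAMF1 4.44-fold higher. Of 23 NF-kB list members 17 rose (adjusted over the list alone, 17 rose and 1 fell; mean 0.99 ± 0.37, adjusted p = 1.25e-13), including NFKB1 (3.36-fold), NFKBIA (3.32-fold) and NFKBIE (2.23-fold). Of 19 CD40 signalling components 9 rose and 2 fell, with the same counts adjusted over the list alone (mean 0.55 ± 0.15, adjusted p = 0.000185): the cytokine-receptor kinase JAK3 rose 8.52-fold, TRAF1 5.70-fold and MAP3K14 3.05-fold. Of 24 negative regulators 10 rose and 3 fell (12 and 4 adjusted over the list alone; mean 0.45 ± 0.18, adjusted p = 0.000369), among them SOCS2 (6.14-fold) and the phosphatases DUSP4 (2.65-fold) and DUSP5 (2.62-fold). Cytokines were mixed, with 7 of 24 higher and 2 lower, also adjusted over the list alone; IL32 rose 5.99-fold and IL15, which sustains lymphocytes, 5.49-fold (mean 0.68 ± 0.11, adjusted p = 0.00114, adjusted p = 0.283 with an estimated correlation).

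Antigen presentation by MHC class I rose as a group at 24 h, with 12 of 19 members higher and none lower (13 and 2 adjusted over the list alone; mean 0.52 ± 0.16, adjusted p = 5.91e-09). The proteasome activators PSME2 and PSME1 rose 3.32-fold and 1.99-fold, TAP2, a subunit of the peptide transporter, 2.48-fold and TAPBP, which loads peptides, 1.63-fold. Of 19 interferon-gamma-type genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; mean 0.68 ± 0.29, adjusted p = 7.88e-05), with GBP1 5.67-fold, IRF1 3.17-fold and the proteasome subunit PSMB9 1.73-fold higher. Of 20 genes of cholesterol synthesis and uptake 16 rose and none fell (17 adjusted over the list alone; mean 0.71 ± 0.25, adjusted p = 7.18e-09, adjusted p = 0.209 with an estimated correlation), including SQLE (2.91-fold), DHCR7 (2.38-fold), FDPS (2.37-fold) and SC5D (2.20-fold), all enzymes of sterol synthesis. On the same arrays the difference between the 3' and 5' control probe sets of ACTB was 1.35 ± 0.25 with sCD40L and 1.96 ± 0.49 with vehicle (log2, SD, n = 5). It was taken as a measure of RNA quality. The 3' signal was 13.22 with sCD40L and 13.23 with vehicle, the 5' signal 11.87 ± 0.25 and 11.27 ± 0.52. The difference thus followed the 5' signal, and a change of the ACTB transcript itself was not tested.

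Uptake receptors of immature DC fell at 24 h: 17 of 26 were lower and 1 higher (19 and 1 adjusted over the list alone; mean -0.68 ± 0.35, adjusted p = 6.53e-08, adjusted p = 0.0744 with an estimated correlation). The sialic acid receptor SIGLEC1 fell by 1.24, the scavenger receptors STAB1 and MSR1 by 1.2 and 1.41, and FCER1G, the signalling chain of Fc receptors, by 0.63. Macrophage markers fell alongside, with 10 of 12 lower and none higher (11 adjusted over the list alone; mean -0.87 ± 0.33, adjusted p = 1.35e-06). These included the complement genes C1QB, C1QC and C1QA, which fell by 1.13, 1.02 and 0.97. MRC1, STAB1 and CD163 belong to both lists. Of 21 unfolded protein response genes 12 were lower than in vehicle at 24 h and 1 was higher (15 and 1 adjusted over the list alone; mean -0.47 ± 0.17, adjusted p = 2.01e-05, adjusted p = 0.0816 with an estimated correlation). In vehicle itself this list rose from 1 h to 24 h by more than this difference, as given below. With sCD40L at 24 h the list mean thus lay above that of vehicle at 1 h, a comparison that was not tested. The lower values are a difference from vehicle at 24 h and not a fall of the list mean below vehicle at 1 h. Single genes were not compared in this way. Lower than in vehicle at 24 h were the chaperone HSPA5 by 1.07, the stress-induced factor DDIT3 by 1.59, SESN2 by 0.74 and the disulfide isomerase PDIA4 by 0.70. The ACTB difference between 3' and 5' probe sets was also lower with sCD40L on these arrays, by -0.60 ± 0.26 (SD, n = 5 donors; exact paired permutation p = 0.0625, two-sided, the smallest that 5 pairs allow), while that of GAPDH differed by -0.031 ± 0.088.

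With the ACTB difference as a covariate, 1170 genes passed at 24 h instead of 3427, 598 of them higher. No list call at 24 h was lost with it, but the cholesterol mean was 0.44 (adjusted p = 0.00162), and 7 named genes no longer passed. Their log2 differences (SE) went from 1.54 ± 0.32 to 0.75 ± 0.52 for SQLE (adjusted p = 0.428), from 1.13 ± 0.24 to 0.66 ± 0.39 for SC5D (0.335), from 1.25 ± 0.25 to 0.89 ± 0.42 for DHCR7 (0.204) and from 1.24 ± 0.21 to 1.07 ± 0.36 for FDPS (0.0678). Those of SESN2, CCL2 and DHRS2 went from -0.74 ± 0.12 to -0.44 ± 0.19 (0.157), from -1.97 ± 0.46 to -2.13 ± 0.80 (0.102) and from -2.12 ± 0.40 to -2.13 ± 0.70 (0.0601). Over all alternatives the adjusted p of these 7 genes lay between 2.17e-08 and 0.428, and that of the cholesterol list between 1.8e-14 and 0.00162. The count at 24 h was 1430 without the donor block, where PDK4, DHRS2, SIGLEC1, MSR1 and DUSP4 were lost (0.0599 to 0.217), 2181 without replicate 4, 2283 without replicate 5 and 2258 with the 24 h arrays alone. No other named gene call at 24 h was lost under an alternative that kept the donor block. Of 3 other kept probe sets of STAB1 1 pointed the opposite way. In DHRS2, LRRK2, JAK3, GBP1 and DDIT3 the difference of 1 donor stood apart from the other 4 (Dixon's ratio 0.721, 0.735, 0.735, 0.736 and 0.776).

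**Figure D3:**
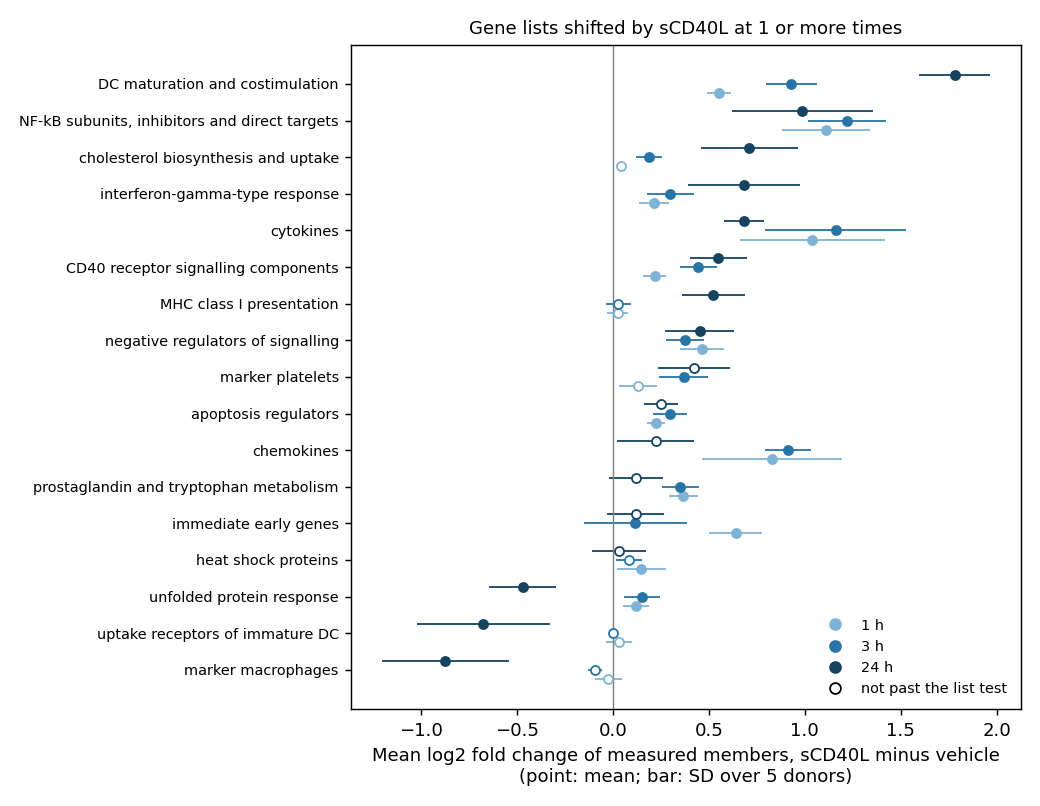
Mean log2 fold change (sCD40L minus vehicle) of the measured members of each gene list that passed the list test at 1 or more times (points are means over the list, bars the SD over 5 donors, open points did not pass). DC maturation rose from 0.55 at 1 h to 1.78 at 24 h, and the unfolded protein response, uptake receptor and macrophage lists lay below 0 at 24 h.

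Some lists passed early and not at 24 h, and others passed at no time. At 24 h the chemokines had 5 of 22 members higher and 3 lower (mean 0.22, adjusted p = 0.115). Immediate early genes (0.12, 0.0634), apoptosis regulators (0.25, 0.085), prostaglandin and tryptophan genes (0.12, 0.534), heat shock proteins (0.032, 0.405) and platelet markers (0.42, 0.165) likewise did not pass at 24 h. Of lists that passed at no time, the MHC class II list had 2 of 21 members higher and 8 lower at 24 h (mean -0.17, adjusted p = 0.0696). Type I interferon genes had 7 of 33 higher and 8 lower (-0.038, 0.671), and CD1 and IL-4-responsive genes 3 of 17 higher and 8 lower (-0.30, 0.189). Chemokine and chemoattractant receptors had 2 of 14 higher and 3 lower (0.029, 0.959), LXR and PPAR targets 2 of 19 higher and 4 lower (-0.22, 0.671), and oxidative stress and metallothionein genes 2 of 18 higher and 4 lower (-0.43, 0.219). Actin and podosome genes had 5 of 25 higher and 5 lower (0.14, 0.24), the cell cycle list 3 of 27 higher and 3 lower (0.079, 0.276), glycolysis and hypoxia genes 2 of 26 higher and 1 lower (-0.056, 0.923) and oxidative phosphorylation 1 of 26 lower (-0.035, 0.959). Markers of monocytes (-0.27, 0.477), neutrophils (-0.45, 0.0797), T cells (0.022, 0.534), B cells (0.12, 0.4), NK cells (0.16, 0.189) and plasmacytoid DC (0.10, 0.361) did not pass. The 4 measured erythroid markers, too few for the test, had a mean of 0.044 at 24 h. In all, 36 of 99 list tests passed, 33 higher and 3 lower with sCD40L than with vehicle. These are not separate findings, since lists share members. TNFAIP3, TNIP1 and NFKBIA are in the NF-kB and negative regulator lists, and TRAF1 and BIRC2 in the NF-kB and CD40 signalling lists. BCL2A1 is in the NF-kB and apoptosis lists, and EBI3 in the maturation and cytokine lists.

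In some lists the mean and the median or the test had different signs. At 24 h this held for chemokine receptors (median -0.18), type I interferon genes (test upward), and at 3 h for the apoptosis regulators given above, uptake receptors (mean 0.00077, median -0.068) and MHC class I (mean 0.029, median -0.022). It also held at 3 h for chemokine receptors (0.034, -0.15), heat shock proteins (0.084, -0.0061), type I interferon genes, LXR and PPAR targets, macrophage markers and T-cell markers (tests upward, means below 0), and monocyte markers (0.017, -0.014). At 1 h it held for chemokine receptors (0.018, -0.066), MHC class I (0.025, -0.0098) and the oxidative stress and macrophage lists (tests upward, means of -0.00065 and -0.023). None of these passed, apart from the apoptosis list at 3 h.

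The effect of sCD40L itself changed with time. Between 1 h and 3 h it differed for 61 genes, in the direction of a rise for 37 and of a fall for 24. The balance turned with the arrays of the compared times alone (120 and 154), with a block for each donor and time (133 and 154) and with array weights (173 and 188), and was 22 and 22 without replicate 2. NXN, SGPP2, PLAT and ELOVL7 gained 14.4-fold, 13.8-fold, 11.2-fold and 5.65-fold, and the transcription factor HIVEP2 3.52-fold. The effect on ZFP36 dropped by 1.52 on the log2 scale, on the growth factor PDGFB by 1.25, on TRERF1 by 1.2, on SLF1 by 1.07 and on STEEP1 by 1.00. Of these 10, NXN and SGPP2 passed without each replicate in turn. Without replicate 4, PLAT (adjusted p = 0.159), ELOVL7 (0.0929), HIVEP2 (0.272), ZFP36, PDGFB and STEEP1 (each 0.0983), TRERF1 (0.246) and SLF1 (0.093) were lost and 2 genes passed. The count was 8, 13 and 7 without replicate 1, 3 and 5: ZFP36 (0.0658, 0.0795 and 0.0942), PDGFB (0.0596, 0.0795 and 0.126), TRERF1 (0.217, 0.101 and 0.187), SLF1 (0.219, 0.174 and 0.19) and STEEP1 (0.0596, 0.151 and 0.137) were then lost. So were HIVEP2 without replicate 1 or 5 (0.206 and 0.167), PLAT without replicate 3 or 5 (0.104 and 0.0946) and SLF1 without replicate 2 (0.0538). PDGFB, with 1 of 3 other probe sets opposed, was at -0.76 without _x_ and _s_ probe sets (0.136). The adjusted p of the 10 genes lay between 1.7e-08 and 0.327 over the alternatives, and without the donor block 6 genes passed, with NXN, SGPP2 and ELOVL7 among the 10. TRERF1 was also lost with no filter (0.069), all kept probe sets (0.053), a second quantile normalization (0.0593), both centrings (0.0529 and 0.052) and the ACTB covariate (0.0566). HIVEP2 and SLF1 were lost with no filter (0.0505 and 0.058), SLF1 with arrays centred on the tested genes (0.0512) and PDGFB with the mean of its probe sets (0.181). With arrays centred on the tested genes 72.7% of the genes called were in the direction of a rise instead of 60.7%.

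From 3 h to 24 h the effect differed for 1206 genes, 655 in the direction of a rise and 551 of a fall (601 and 627 with arrays centred on the tested genes). EDIL3 gained 14.8-fold, PTPRK 12.4-fold, CNN3 11.9-fold, IDO1 10.6-fold and SLCO5A1 10.4-fold. The effect on NXN dropped by 3.66 on the log2 scale, on KANK1 by 3.53, on IL1A by 3.45, on PLAT by 3.04 and on CCL20 by 2.90. From 1 h to 24 h it differed for 1518 genes, 677 upward and 841 downward, a balance that turned to 278 and 198 with the ACTB covariate, to 117 and 82 without the donor block and to 330 and 329 without replicate 4. CYP7B1 gained 29.3-fold, CNN3 21.0-fold, EBI3 17.6-fold, MMP10 15.3-fold and PTPRK 14.2-fold, whereas the effect dropped by 3.71 on IL1A, 3.08 on TNF, 3.06 on CCL20, 2.93 on PTGS2 and 2.73 on IL1B. All of these had adjusted p of at most 0.00704 and the same sign in 5 of 5 donors.

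With the ACTB covariate, which lowered the counts to 309 (24 h against 3 h) and 476 (24 h against 1 h), 4 named genes were lost in the first difference and 5 in the second. In the first, IDO1 went from 3.41 ± 0.64 to 2.73 ± 0.94 (log2, SE; adjusted p = 0.129), IL1A from -3.45 ± 0.64 to -2.58 ± 0.92 (0.142), PLAT from -3.04 ± 0.68 to -2.24 ± 0.98 (0.238) and CCL20 from -2.90 ± 0.61 to -1.58 ± 0.82 (0.335). In the second, IL1A went from -3.71 ± 0.64 to -2.94 ± 0.87 (0.0607), TNF from -3.08 ± 0.72 to -2.33 ± 0.99 (0.207), CCL20 from -3.06 ± 0.61 to -1.89 ± 0.77 (0.191), PTGS2 from -2.93 ± 0.69 to -1.75 ± 0.90 (0.316) and IL1B from -2.73 ± 0.62 to -2.41 ± 0.87 (0.128). Without replicates 1, 4 and 5 the counts were 677, 459 and 521 for the first difference and 966, 659 and 641 for the second, where TNF was lost without replicate 4 (0.0521) and TNF, PTGS2 and IL1B without replicate 5 (0.0661, 0.0647 and 0.0638). Without _x_ and _s_ probe sets the differences for IL1A were -0.17 (0.716) and -0.46 (0.191), and that for KANK1 was 0.13 (0.755). Over the alternatives, the adjusted p of the genes named so far in this paragraph lay between 2.47e-06 and 0.755 for the first difference. For the second it lay between 4.99e-05 and 0.316. Without the donor block 178 and 199 genes passed, SLCO5A1 (0.0909) and PLAT (0.065) being lost in the first, and with the arrays of the compared times alone 778 in the first.

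Expression also differed between times in the vehicle arrays. Between 1 h and 24 h 3153 genes differed, 1553 higher and 1600 lower at 24 h (49.3% higher). The share was above 50% without the donor block (51.8%), with the arrays of the compared times alone (51.4%), with no filter (50.4%), with a log2 fold change of at least 1 (63.1%), without replicates 1, 2 and 5 (52.6%, 50.9% and 51.2%), with the ACTB covariate (50.3%) and with arrays centred on the tested genes (51.3%). TMEM45A rose 21.7-fold (log2 difference 4.44 ± 0.48, SE, n = 5), the glycolytic enzyme ENO2 12.2-fold and DDIT4, an inhibitor of mTOR signalling, 9.87-fold and the lipid-droplet protein HILPDA 8.95-fold. NUPR1, a stress-response nuclear protein, rose 9.55-fold, SLAMF9 9.04-fold, the chaperone CLGN 8.79-fold and the collagen-modifying enzyme PLOD2 7.47-fold. Among the decreases, FOSB fell by 3.55 on the log2 scale, NR4A2 by 2.84, EGR3 by 2.09, NFKBIZ by 2.47, the growth factor HBEGF by 1.97 and CD69 by 1.87. HS3ST3B1 fell by 1.94 and MAP7 fell by 1.93. CD69 was lost without the donor block (adjusted p = 0.0841; 3.95e-05 to 0.0841 over the alternatives). With the block, each of these genes had the same sign in 5 of 5 donors, with adjusted p of at most 0.000851.

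As groups, glycolysis and hypoxia-response genes rose in vehicle cells at 24 h (21 of 26 higher, none lower, 22 adjusted over the list alone; mean 0.90 ± 0.20, adjusted p = 2.51e-17), as did the unfolded protein response (16 of 21 higher and 1 lower, 18 and 1 adjusted over the list alone; mean 0.73 ± 0.058, adjusted p = 2.71e-11). Oxidative phosphorylation genes fell (12 of 26 lower and 1 higher, 16 and 1 adjusted over the list alone; mean -0.19 ± 0.067, adjusted p = 0.000112), and so did immediate early genes (10 of 25 lower and 2 higher, 13 and 2 adjusted over the list alone; mean -0.62 ± 0.20, adjusted p = 0.00114), with adjusted p = 0.559 and 0.418 with an estimated correlation. Oxidative stress genes (8 of 18 higher and 1 lower; mean 0.72, adjusted p = 0.000955) and LXR and PPAR targets (8 of 19 higher and 1 lower; 0.43, 0.0394) also passed, with adjusted p = 0.545 and 0.418 with an estimated correlation. So did falls of macrophage markers (5 of 12 lower; -0.45, 0.0172), type I interferon genes (7 of 33 lower and 1 higher; -0.22, 0.0325) and heat shock proteins (5 of 15 lower; -0.20, 0.0492), with adjusted p = 0.439, 0.712 and 0.69 with an estimated correlation. Adjusted over the list alone, these 5 lists had 9 higher and 1 lower, 8 higher and 2 lower, 7 lower, 7 lower and 1 higher, and 5 lower. The difference between 3' and 5' control probe sets was 0.65 ± 0.025 for GAPDH in vehicle at 24 h and 0.96 ± 0.096 at 1 h (SD, n = 5), and for ACTB 1.96 ± 0.49 and 1.71 ± 0.37.

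Between 1 h and 3 h of vehicle 28 genes differed, 27 of them higher at 3 h. ANKRD37 rose 4.70-fold, CSF1 2.79-fold, the stress factor DDIT3 2.57-fold, CHST15 2.35-fold, LRIG2 2.17-fold, the growth factor PDGFA 2.14-fold, TMEM51 2.07-fold and JUN 1.90-fold, with adjusted p from 0.0129 to 0.0477. The single gene that was lower, NR4A2 (-1.32, adjusted p = 0.0145), lies outside the naming rule and was chosen after its values were seen. Glycolysis and hypoxia-response genes had 3 of 26 members higher (6 adjusted over the list alone; mean 0.40 ± 0.21, adjusted p = 6.39e-08, adjusted p = 0.19 with an estimated correlation). Cholesterol genes (0 of 20 past the threshold, 1 higher and 1 lower adjusted over the list alone; mean 0.18, adjusted p = 0.0496) and type I interferon genes (0 of 33, also adjusted over the list alone; -0.13, 0.0498) passed the list test by little, with adjusted p = 0.767 for both with an estimated correlation.

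The count of this comparison moved with every donor left out. Of the 28 genes, 21 had the same sign in all 5 donors. With limma the count was 0 without replicate 1, 2, 4 or 5, with 1024, 893, 817 and 839 genes at an unadjusted p below 0.05, and 171 without replicate 3. With all donors 1194 genes were at that unadjusted level. The adjusted p of ANKRD37 was 0.122, 0.205, 0.372 and 0.288 without replicates 1, 2, 4 and 5, and all 8 named genes were lost in each of these. Without the donor block 7 of the 8 were lost, all but ANKRD37. With the ACTB covariate DDIT3, CHST15 and TMEM51 were lost (0.067, 0.0607 and 0.067), at 1.34 ± 0.29, 1.2 ± 0.26 and 1.06 ± 0.23 against 1.36 ± 0.28, 1.23 ± 0.25 and 1.05 ± 0.22 (SE). With the arrays of the compared times alone DDIT3, LRIG2 and TMEM51 were lost (0.0527, 0.0509 and 0.0607), and with no filter DDIT3, CHST15 and TMEM51 (0.0515, 0.0512 and 0.0644). TMEM51 was also lost with all kept probe sets (0.0548) and with arrays centred on the tested genes (0.0518). With the mean of a gene's probe sets DDIT3 (0.0526), CHST15 (0.064) and TMEM51 (0.0613) were lost, CSF1 was at 0.64 (0.277) and PDGFA, with 1 of 2 other probe sets opposed, at 0.65 (0.129). Over all alternatives the adjusted p of the 8 genes lay between 6.31e-07 and 1.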

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

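The Dixon rule and the tests of differences between times were fixed before the data were examined, and no test of this part was chosen after its result was seen. Chance gives about 1 in 20 groups past Dixon's critical value, and 16 of 306 groups of 5 donors' differences tested lay past it (12 of 183 for named genes, 4 of 99 for list means, 0 of 24 for array measures).

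In each case the difference of 1 donor between sCD40L and vehicle lay far from that of the other 4. At 1 h the ratio of the gap to the range was 0.774 for EREG, 0.772 for IRF1, 0.772 for HSPB1, 0.731 for PTGER4, 0.798 for the T-cell marker list and 0.726 for the platelet marker list. At 3 h it was 0.781 for SGPP2, 0.74 for IL1B, 0.754 for DUSP2 and 0.873 for the type I interferon list. At 24 h it was 0.721 for DHRS2, 0.735 for LRRK2, 0.735 for JAK3, 0.736 for GBP1, 0.776 for DDIT3 and 0.817 for the cell cycle list.

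The effect of sCD40L itself differed between times for 61 genes (3 h and 1 h), 1206 genes (24 h and 3 h) and 1518 genes (24 h and 1 h). Some named genes passed the threshold in opposite directions at 2 times, with the difference also past it. All were higher with sCD40L at the earlier time and lower at 24 h. Between 24 h and 3 h these were XBP1 (-1.06, adjusted p = 0.00295) and PTGER2 (-1.73, adjusted p = 4.79e-05). Between 24 h and 1 h they were PTGER2 (-1.81, adjusted p = 2.09e-05) and PDGFB (-1.96, adjusted p = 5.78e-06). KANK1 met the same rule between 24 h and 3 h (-3.53, adjusted p = 8.8e-06), with a value that 2 other probe sets of the gene did not share.

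List means, tested with limma on the 5 donors, differed as follows (log2, later minus earlier time). Between 3 h and 1 h the immediate early list dropped by 0.523 (-0.523, adjusted p = 0.0324). Between 24 h and 3 h DC maturation gained 0.85 (adjusted p = 4.99e-05), MHC class I 0.494 (8.01e-06), the interferon-gamma-type list 0.384 (0.0141) and the cell cycle list 0.209 (0.0225). In the same interval the lower values were -0.779 for macrophage markers (2.57e-05), -0.69 for chemokines (0.0273), -0.676 for uptake receptors (0.000389), -0.621 for the unfolded protein response (1.91e-05), -0.517 for oxidative stress genes (0.0486), -0.282 for monocyte markers (0.0027) and -0.23 for prostaglandin and tryptophan genes (0.0225).

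Between 24 h and 1 h DC maturation gained 1.23 (adjusted p = 5.32e-07), cholesterol genes 0.667 (0.0229), MHC class I 0.499 (3.4e-06), the interferon-gamma-type list 0.471 (0.0026), CD40 signalling components 0.332 (0.00424) and platelet markers 0.29 (0.00893). The lower values were -0.85 for macrophage markers (6.79e-06), -0.709 for uptake receptors (0.000215), -0.606 for chemokines (0.0435), -0.589 for the unfolded protein response (2.12e-05), -0.519 for immediate early genes (0.00436), -0.246 for prostaglandin and tryptophan genes (0.0103), -0.227 for monocyte markers (0.0103) and -0.192 for MHC class II (0.0201).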

How the results depend on the processing

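The covariate for the ACTB 3' minus 5' difference and the centring on tested genes were chosen after seeing the data; the other alternatives were planned. Counts are given in the order 1 h, 3 h, 24 h, the differences 3 h and 1 h, 24 h and 3 h, 24 h and 1 h, vehicle 3 h and vehicle 24 h, against 270, 1923, 3427, 61, 1206, 1518, 28 and 3153. With no replicate block they were 114, 708, 1430, 6, 178, 199, 4 and 1323. The donor pairs the arrays, and without that pairing 52 of the 220 named gene results past the threshold were lost. With a log2 fold change of at least 1 they were 93, 258, 591, 25, 405, 508, 13 and 350, by construction a subset.

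Other counts moved by over 1.5 times were as follows, and the cause was not tested. All kept probe sets, a larger number of tests, gave 428 (1 h), 2925 (3 h), 5585 (24 h), 2319 (24 h and 1 h) and 5395 (vehicle 24 h). Array weights gave 535 (1 h), 361 (3 h and 1 h) and 431 (vehicle 3 h), the arrays of the compared times alone 2258 (24 h), 274 (3 h and 1 h) and 778 (24 h and 3 h), and a block for each donor and time 287 (3 h and 1 h) and 1824 (24 h and 3 h). No filter gave 36 (3 h and 1 h) and 13 (vehicle 3 h), the stricter filter 99 and 43. For vehicle 3 h the mean of probe sets gave 14, no _x_ and _s_ probe sets 15, and trend and robust options 45. The ACTB covariate gave 1170 (24 h), 309 (24 h and 3 h), 476 (24 h and 1 h) and 17 (vehicle 3 h). The main fit takes 1 spread per gene for all times. With the arrays of the compared time alone the count was 402 instead of 270 at 1 h and 2324 instead of 1923 at 3 h. At 24 h it was 2258 instead of 3427. Array weights moved these counts the same way (535, 2814 and 2526). SEs and p-values of the main fit may thus be too small at 24 h and too large earlier, which was not tested.

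Without 1 replicate the counts ranged from 157 to 244, 1023 to 1604, 2181 to 3315, 2 to 44, 459 to 1181, 641 to 1347, 0 to 171 and 2104 to 2672. The limma count of 0 for vehicle 3 h came without replicate 1, 2, 4 or 5, with 1024, 893, 817 and 839 genes at an unadjusted p below 0.05. The lowest values came without replicate 5 (157 and 641), replicate 4 (1023, 2181, 2 and 459) and replicate 2 (2104). Counts more than 1.5 times below the full ones also came without replicate 1 (1177, 8, 677 and 966), 3 (13), 4 (659) and 5 (1280, 2283, 7 and 521).

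With arrays centred on the tested genes 782 genes were higher and 945 lower at 3 h (45.3% higher, against 34.8%, and 30.9% with arrays centred on their medians), and 40 higher and 15 lower for 3 h and 1 h (72.7%, against 60.7%). KANK1 changed sign without _x_ and _s_ probe sets, to -0.015 at 3 h and 0.133 between 24 h and 3 h, since another probe set then stands for the gene. For named genes under all alternatives, 4168 values stayed on their side of the threshold, 209 passed no longer and 30 passed anew. The 2 values of KANK1 that changed sign were counted apart. A change of sign where neither fit passed was not counted. Of the list values 624 stayed and 24 passed no longer. The 36 list shifts stayed between 33 and 47. Nonspecific probe sets had a median of 2.52 against array medians near 5.1, so changes of genes near that level are compressed or missed.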

Other observations

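The groups by gene symbol, the zinc finger pattern and the 2 scaling tests were chosen after the data were seen, the bounds and the reading of the scaling tests also after their result; the count of genes with the ACTB covariate was seen before its bound was set, and the tests of zinc finger genes, of ACTB slopes and of other splits were fixed before their results were seen.

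Genes were also grouped by the stem of their symbol, in 65 groups. Interleukins and their receptors (stem IL, 60 genes) rose at each time: 7 were higher and 0 lower at 1 h, 12 and 0 at 3 h, and 22 and 3 at 24 h, with limma. The means were 0.33 ± 0.090, 0.44 ± 0.10 and 0.40 ± 0.053 (SD, n = 5), with the same sign in 5 of 5 donors (camera adjusted p = 0.000367, 5.68e-06 and 2.76e-05). The dual-specificity phosphatases (stem DUSP, 22 genes), some of which remove phosphate from MAP kinases, had 6 members higher and 2 lower at 24 h (mean 0.27, adjusted p = 0.0233, adjusted p = 0.0528 with an estimated correlation).

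The 50 genes of the large subunit of mitochondrial ribosomes (stem MRPL) had a mean of -0.11 at 1 h, where 1 was lower and 0 higher with limma (adjusted p = 0.00199, adjusted p = 0.609 with an estimated correlation) and of -0.15 at 3 h, where 9 were lower and 1 higher (adjusted p = 0.0254, adjusted p = 0.708 with an estimated correlation). The 27 of the small subunit (stem MRPS) had a mean of -0.11 at 1 h, where 1 was lower and 0 higher (adjusted p = 0.0233, adjusted p = 0.554 with an estimated correlation), and did not pass at 3 h (mean -0.17, 6 lower and 0 higher, adjusted p = 0.0624).

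Zinc finger genes (stem ZNF, 398 genes) were lower at 1 h, with 38 past the threshold in that direction and 2 in the other (9.55% lower, against 0.56% of other genes; mean -0.188, camera adjusted p = 5.65e-12, adjusted p = 0.00689 with an estimated correlation). Dim expression alone did not account for it, since the central 95% of 10000 sets matched on expression had means between -0.0182 and 0.028. These sets were drawn at random, so that interval does not allow for correlation among zinc finger genes. Probe sets marked _x_ or _s_ did not either, since without them the mean was -0.198. Cross-hybridisation of unmarked probe sets was not tested. A single donor did not account for the lower ZNF mean, which lay below that of matched genes in 5 of 5 donors (-0.192 ± 0.0656, SD). At 3 h and 24 h the means (-0.127 and -0.164) also lay below the central 95% of matched sets (-0.0636 to 0.00381, and -0.0717 to 0.0165). The ZNF mean lay below that of matched genes in 5 of 5 donors at both times. The set did not pass at either (camera adjusted p = 0.229 and 0.0759, adjusted p = 0.697 and 0.536 with an estimated correlation). The share called lower was then 10.3% against 8.71% of other genes, and 16.1% against 14.9%.

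More genes were lower than higher at 3 h (34.8% higher) and 24 h (37.7% higher). Quantile normalization could bring this about where large increases push other genes down. With arrays centred on the tested genes the share was 45.3% at 3 h (45.7% to 51.6% without each donor in turn) and 42.1% at 24 h (42.6% to 43.7%), but this centring moves the balance towards 50% by construction and left a median change of -0.0182 at 24 h. Centring on array medians gave 30.9% and 34.8%, a second quantile normalization 38.7% and 41.7%, and the ACTB covariate 51.1% at 24 h. The distribution of the arrays also moved with sCD40L, with the same sign in each donor. The interquartile range changed by -0.0548 at 3 h and -0.0714 at 24 h, and the array median by 0.0192 and 0.0156. Array scaling and a true excess of lower genes cannot be told apart at either time, because the values used here were all normalized and RNA per cell was not among them.

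At 24 h the ACTB 3' minus 5' difference was lower with sCD40L in the 5 donors' mean (-0.604 ± 0.255, SD), from a higher 5' signal, and a difference in RNA quality could add to the 24 h calls. With that difference as a covariate, 1042 of the 3427 genes passed in the same direction (497, 712, 1249, 445 and 266 without replicates 1 to 5). These 1042 were picked by passing this fit, which takes 1 slope per gene for all times. Their passing counts only against a linear trend of that form as the whole cause. It does not exclude other effects of RNA quality on them. The other 2385 no longer passed: their median change in the called direction went from 0.499 to 0.446 and the median SE from 0.137 to 0.229, so calls ended mostly through the wider error. For these 2385 an RNA quality effect and an sCD40L effect cannot be told apart, because the ACTB difference goes with treatment at 24 h; slopes on it at 1 h and 3 h predicted the sign of 45.1% of the 24 h changes, but had equal signs at the 2 times for 50.7% of genes, which voids that test. The GAPDH difference moved by -0.0305 ± 0.0877, and a change of the ACTB transcript itself was not tested.

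Labels were also reassigned in 100 splits, the real one included, of the 10 arrays compared or, for the differences between times, of the 10 donor pairs of 2 times (20 arrays). The real split gave the most genes in each of the 8 comparisons. The real value and the highest other were 270 and 61 at 1 h, 1923 and 385 at 3 h, and 3427 and 2289 at 24 h. For the differences they were 61 and 1 (3 h and 1 h), 1206 and 19 (24 h and 3 h) and 1518 and 1 (24 h and 1 h), and for vehicle 28 and 8 (3 h) and 3153 and 896 (24 h). Most of these splits, unlike the paired design, put both arrays of at least 1 donor on the same side. The 16 splits that part all 5 donors are too few for a share under 0.05; the real split gave the most genes of them in each comparison, and the highest others were 7, 1, 1268, 0, 1, 0, 7 and 122 in that order.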
